A study of Homo sapiens with 8 samples.

How the data were processed

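Gene expression was measured in U87 cells, an established human glioma line, on single-colour oligonucleotide arrays. There were 4 treatment groups: untreated cells, cells given 50 µM of a compound that binds the minor groove of DNA (called the ligand here, as the labels do not name it), cells exposed to 8.5 Gy of ionizing radiation, and cells given the ligand 1 h ahead of 8.5 Gy. Per the labels, cells had been plated for 24 h when treatment began and RNA was taken 4 h after treatment. Per the labels' protocols, mRNA was copied by linear amplification to aminoallyl RNA and labelled with Cy3.

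The 8 arrays were 2 per group, 1 on each of 2 array designs, called design A and design B here. Each design carried 19700 probes and the designs shared 0 identifiers, so no probe was measured more than once per group. Whether both arrays of a group received the same RNA is not given in the sources used here. Every comparison between groups therefore set 1 array against 1 array, within a design, and no replicate of any group was available for a probe.

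The deposited spot values were in linear intensity units, from 1 file per array. Background subtraction, scanner settings and any scaling between arrays are not given in the sources used here. The lowest value, 0.001, occurred on 1 probe of the radiation array and 1 probe of the combination array of design B. In the combination array of design B, 2 probes exceeded 65535, the ceiling of a 16-bit scan, and reached 198942. Values on exact multiples of 0.5 made up between 3.36% and 30.6% of an array.

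The authors' second deposited table held a standardized score for each probe and array. Set against the intensities of the same arrays, each score equalled log2 intensity minus a median, divided by a median absolute deviation, to within 5.00e-05, the rounding of the table. A single median and a single deviation per group had been taken over both array designs together. The medians were 217.94, 189.24, 205.825 and 208.65 intensity units in control, ligand, radiation and combination, and the deviations were 0.64, 0.70, 0.66 and 0.75 on the log2 scale. The median score per array was -0.05, -0.62, -0.37 and -0.66 in design A and 0.03, 0.54, 0.33 and 0.42 in design B, in the same order of groups. These scores served as an alternative source of values, multiplied by the mean deviation of 0.69 to bring them near the log2 scale. As each group had been divided by its own deviation, 2-fold in these values only approximates 2-fold in the main setting.

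The main setting took log2 of the deposited intensities and quantile normalized the 4 arrays of each design. Probes were kept when their mean over the 4 arrays lay above the median of their design, which left 9850 probes per design and 19700 in all. A probe counted as higher or lower in a comparison when the log2 difference reached 1 (2-fold). No test was applied to a difference of 2 arrays. Across the 4 arrays of a design, limma was used to fit an additive model with a ligand term and a radiation term, which leaves 1 residual degree of freedom. Its p-values were adjusted by the Benjamini-Hochberg method over both designs, with 0.05 as the threshold. The residual in this fit holds measurement noise, culture differences and any non-additive response together. Its p-values set each effect against that mixture between these arrays, not against replicate error. Limma also pools the variance over probes, with a weight (prior degrees of freedom) of 14.1 in design A and 3.43 in design B in the main setting. A standard error given here therefore owes more to the pool than to the probe itself, above all in design A. Each treatment effect was also read as 2 differences that share no array, without and with the other treatment. The number of probes past 2-fold in both was set beside the number expected if the 2 lists were independent. Correlations between the 2 differences run across probes, which are not independent replicates.

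The files do not pair probe identifiers with genes, and 0 entries of the gene table used here carried such an identifier. For this reason 28 gene lists and a set of single genes chosen before the data were examined could not be evaluated, and the intensity floor and the naming rule were applied to probes where they had been written for genes. The normalizations, floors, thresholds and tests described here were also chosen before the data were examined, apart from 2 alternatives named in the closing section and the simulation of unchanged probes.

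The naming rule ranked probes for radiation and for ligand. Probes with the same direction in both differences of a treatment were ordered by the smaller of the 2, and the 10 highest and 10 lowest were kept. For combination minus radiation and for the interaction, the 5 highest and 5 lowest were kept. Of each ranking, the leading 2 probes per direction are given by identifier and the others are summarized.

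The fitting and counting steps were tested on simulated data built from the real probe means and residuals, with 200 probes per design given a known radiation effect. Probes simulated at 2-fold passed the 2-fold limit in both radiation differences in 24% of cases in design A and 14% in design B. At 4-fold this share was 96% in both designs, and at 8-fold and 16-fold it was 100%. The limma test called 0% and 18% of the simulated 2-fold probes in designs A and B, 80% and 96% at 4-fold, and 100% at 8-fold and 16-fold in both designs. Among unchanged simulated probes, 0.546% in design A and 0% in design B passed 2-fold in both differences. The noise of every probe and array of a design came from 1 pool, a spread that real probes need not share. These shares therefore do not carry over to the real probes, and an absence of limma calls does not show an absence of large responses. B#16996, at 10.02-fold, and B#27461, at 7.77-fold, were not called for radiation in the main setting.

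In a further simulation, made after the data were seen, the residuals of the additive model among probes above the floor were drawn at random for each array, with no treatment effect, in 200 draws per design. It gives the number of probes past 2-fold in both differences from residual spread alone, and those residuals include any non-additive response. It also gives every array the same spread. The robust standard deviation between arrays ran from 0.31 to 0.66 in design A and from 0.22 to 0.34 in design B. A count outside its range in either design therefore does not by itself show a response or the lack of one.

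Intervals for correlations came from 1000 bootstrap resamples of probes and intervals for robust standard deviations from 200, at the 95% level. The robust standard deviation is the median absolute deviation scaled to a normal distribution. Alternatives covered the deposited scores with and without quantile normalization, median centring, an offset of 50 before log2, no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, each design alone, and limma with an intensity trend and robust variance. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.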

Results

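The arrays recorded the transcripts of U87 glioma cells after a minor groove binding ligand, ionizing radiation, or both. U87 is a long-established line from a human glioblastoma. Compounds that lie in the DNA minor groove are studied as modifiers of the cellular response to radiation, and the design asks how such a ligand alters expression in irradiated cells. Each of the 4 groups had 1 array of design A and 1 of design B. Median intensity in design A was 213.65 in control, 140.015 in ligand, 173.5 in radiation and 148.29 in combination. In design B the medians were 221.265, 245.615, 239.145 and 260.17 in the same order. The single array per group and design limits the precision of every value given here.

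**Figure D1:**
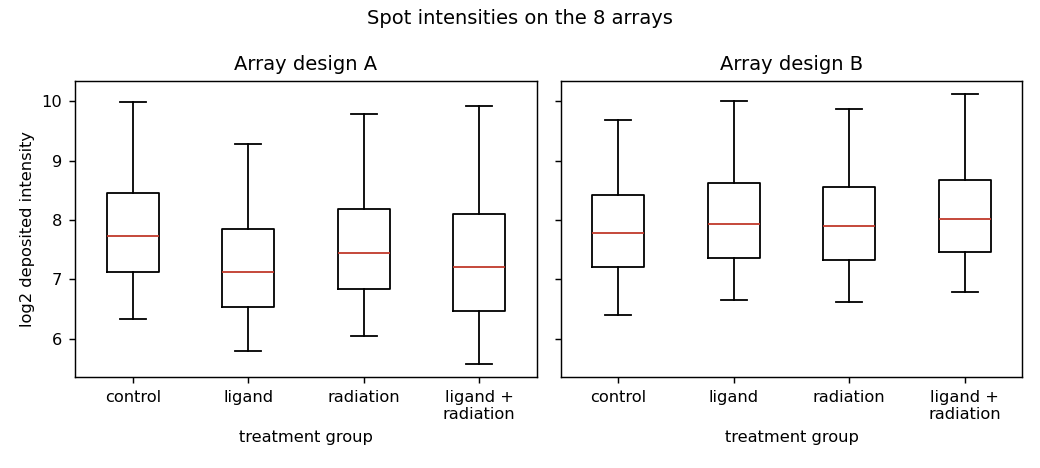
Box plots of log2 deposited intensity for each treatment group, with array design A on the left and design B on the right. Boxes span the quartiles, red lines are medians and whiskers reach the 5th and 95th percentiles of 19700 probes. In design A the control array had the highest median (213.65) and in design B the lowest (221.265).

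After normalization, arrays of design A lay farther apart than arrays of design B. The widest pair was control and ligand in design A, where the robust standard deviation of the log2 differences was 0.66, against 0.27 for the same pair in design B. The closest pair in design A was radiation and combination, at 0.31. In design B both the ligand and the radiation array were at 0.22 from the combination array. Across probes, Pearson r between arrays ran from 0.689 to 0.916 in design A and from 0.861 to 0.924 in design B.

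Radiation alone was compared with untreated cells to find the transcripts that respond to 8.5 Gy within 4 h. The probes with the strongest repeat of direction were B#16996 and B#27461, both lower after irradiation, and A#04902 and A#32685, both higher. B#16996 read 11090.5 intensity units in control and 1120.62 after radiation. With the ligand present it read 15052.3 without and 1785.25 with radiation. Its log2 differences were -3.66 without and -2.99 with ligand. B#27461 showed -2.96 and -2.95. A#04902 was higher by 2.24 without and 3.53 with ligand, and A#32685 by 2.32 and 2.18. The ligand array read 57.01 for A#04902, below that array's lower quartile of 92.925, so its larger difference has no firm size. For A#32685 the control array read 115.86, below that array's lower quartile of 140, so the difference of 2.32 has no firm size either. The files do not pair these identifiers with genes.

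Over both designs, 370 of 19700 probes were at least 2-fold higher and 631 at least 2-fold lower in radiation than in control. At 2-fold the designs went opposite ways, with 220 higher and 572 lower in design A and 150 higher and 59 lower in design B. These counts come from 1 array against 1 array and have no replicate check. At 1.5-fold, more probes were higher than lower in both designs, 1351 against 1173 in design A and 480 against 367 in design B. Above the floor the median difference was 0.16 on the log2 scale in design A and 0.00 in design B, and the design A counts include that shift.

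Irradiated cells given the ligand were compared with ligand-treated cells as a second reading of the radiation effect, on other arrays. In this comparison 581 probes were at least 2-fold higher and 302 lower, and median centring gave 1011 and 263. Design A held 520 of the higher and 136 of the lower probes, and design B held 61 and 166. Probes past 2-fold in the same direction in both radiation differences numbered 13 higher and 24 lower. Independent lists would share 12.5 and 8.89. Median centring gave 29 higher and 21 lower. Opposite directions were more common, with 129 probes against 36.1 expected from independent lists, and 125 of these were in design A. There the simulated unchanged probes gave a mean of 74.8 with opposite directions (95% of draws between 61.0 and 92). In design B, 3 probes were higher in both against 0.929 expected and 9 were lower in both against 0.994 expected. The simulation of unchanged probes gave 1.8 higher and 1.94 lower there, each with 95% of draws between 0 and 5. The 3 higher probes lay inside that range and the 9 lower above it. Simulated unchanged probes gave a mean of 75.3 with the same direction in design A (95% of draws between 60.0 and 92), against 25 observed, and 3.74 in design B (between 1 and 7.03), against 12 observed. The simulation assumed an equal spread on every array, which the arrays of neither design showed. Robust standard deviations between arrays ran from 0.31 to 0.66 in design A and from 0.22 to 0.34 in design B. The design B counts above their ranges therefore do not by themselves show a response.

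Across probes, the 2 radiation differences had a Pearson r of -0.26 and a Spearman rho of -0.26 in design A, and 0.12 and 0.26 in design B. Of 792 probes past 2-fold without ligand in design A, 249 (31.4%) had the same sign with ligand. In design B it was 128 of 209 (61.2%). The design B share was 136 of 315 (43.2%) with the deposited scores and 123 of 204 (60.3%) with median centring. In the limma fit of all 4 arrays, 0 probes passed for radiation at an adjusted p of 0.05, and 896 of 19700 had an unadjusted p under 0.05. These were 2.72% of the probes in design A and 6.38% in design B, where evenly spread p-values would give a fraction of 0.05. With an intensity trend and robust variance, limma called 1 probe, A#04902, and with the deposited scores 82, all on design B. Its radiation effect was 2.88 ± 0.42 (SE), with a limma adjusted p of 0.104 in the main setting, and 2.35 with an offset of 50. For B#16996 the effect was -3.33 ± 0.21 (SE, limma adjusted p = 0.221) and for B#27461 it was -2.96 ± 0.14 (SE, limma adjusted p = 0.112). A#32685 had 2.25 ± 0.39 (SE, limma adjusted p = 0.217), and 1.81 with an offset of 50.

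The 10 probes ranked highest for radiation had effects of 2.31-fold or more, 7 in design A and 3 in design B. The 10 ranked lowest lay between 2.57-fold and 10.02-fold below, 4 in design A and 6 in design B. None of these 20 passed the limma threshold in the main setting, with adjusted p-values between 0.104 and 0.972.

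**Figure D2:**
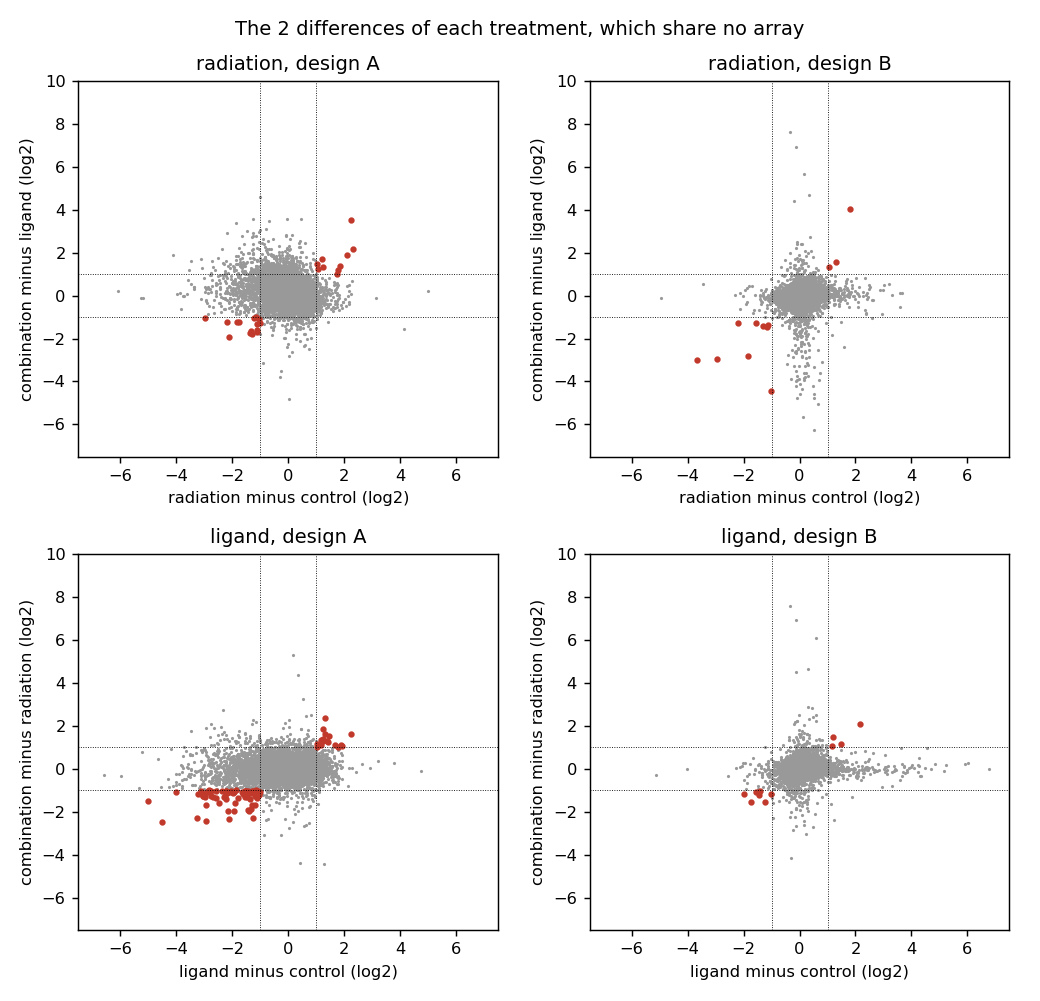
Scatter plots of the log2 differences of each probe above the intensity floor, for radiation (top) and ligand (bottom) in designs A (left) and B (right). The horizontal axis is the difference without the other treatment and the vertical axis the difference with it, dotted lines mark 2-fold, and red points passed 2-fold in the same direction in both. Radiation in design A slopes downward (r = -0.26), while the other panels have r between 0.06 and 0.12.

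The ligand alone was compared with untreated cells to find its own effect on expression. Among probes that kept their direction in irradiated cells, A#02366 and A#11839 were lowest and B#21243 and A#04738 highest. A#11839 fell from 2964.86 intensity units in control to 260.63 with ligand, and from 2788.22 to 516.13 in irradiated cells. Its log2 differences were -2.93 and -2.44, and its ligand effect was -2.69 ± 0.39 (SE, limma adjusted p = 0.0390), 6.43-fold lower. A#02366 was lower in both ligand differences, with an effect of -3.51 ± 0.47 (SE, limma adjusted p = 0.0338). Both ligand-treated readings lay below the lower quartile of their arrays, and with an offset of 50 the effect was -2.78. Its control array, at 2234.51, stood more than 4-fold above the other 3 arrays, which read 73.15, 267.64 and 35.64 in ligand, radiation and combination. B#21243 read 295.3 in control, 1593.39 with ligand, 298.53 after radiation and 1495.43 with both. The log2 differences of B#21243 were 2.17 and 2.08, and its effect of 2.13 ± 0.14 (SE) had a limma adjusted p of 0.187. A#04738 was higher by 2.25 and 1.64, with an effect of 1.94 ± 0.39 (SE, limma adjusted p = 0.292).

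Relative to control, 845 probes were at least 2-fold higher and 1187 at least 2-fold lower with ligand. Most of these were on design A, with 601 higher and 1121 lower, against 244 higher and 66 lower on design B. The majority turned at a 1.5-fold threshold, with 3097 higher and 2098 lower, while the deposited scores gave 565 and 2097 at 2-fold. In the main setting the median difference above the floor was 0.20 on the log2 scale in design A and -0.05 in design B, and the counts include that shift. The limma fit called 3 probes lower with ligand and 0 higher, and 1217 probes had an unadjusted p under 0.05. The 1217 were 6.35% of the probes in design A and 6.01% in design B, where evenly spread p-values would give a fraction of 0.05. The third called probe, at -2.76 ± 0.41 (SE, limma adjusted p = 0.0390), was 6.76-fold lower. Its control array, at 43229, also stood more than 4-fold above the other 3 arrays, which read 2862.91, 9087 and 2244.9, so this held for 2 of the 3 calls. All 3 were on design A and lower in both ligand differences. Under limma with an intensity trend and robust variance, with median centring and with cyclic loess, 0 probes were called for the ligand. With the deposited scores 89 were called higher and 10 lower, all on design B. Without probes apart on 1 array, 3 were called higher and 41 lower, and with the floor at the 75th percentile 1 higher and 25 lower. In design A these 2 settings raised limma's prior degrees of freedom from 14.1 to 49.9 and 32.9. Leaving out probes apart on 1 array removes large residuals, so the larger number of calls there is no further support.

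**Figure D3:**
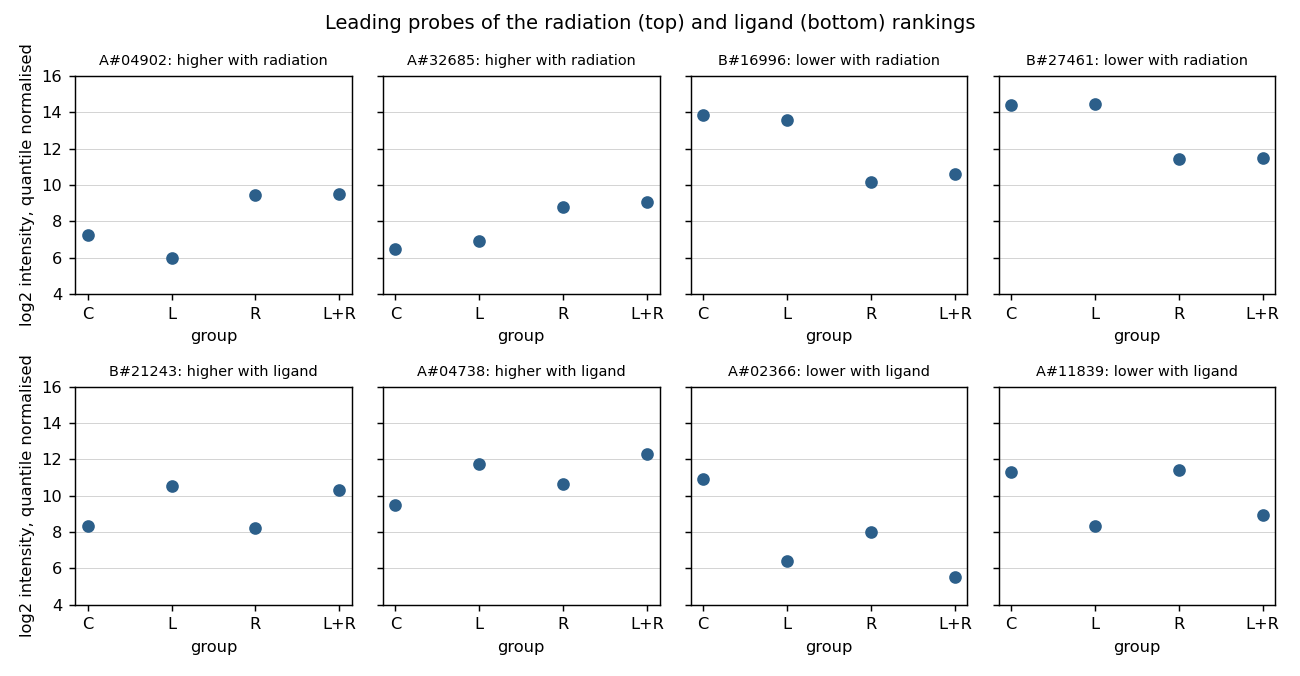
Log2 intensity after quantile normalization in control (C), ligand (L), radiation (R) and combination (L+R) for the leading probes of the radiation ranking (top) and the ligand ranking (bottom). Each point is 1 array, so no error bar is drawn. B#21243 is higher in both ligand-treated groups, with differences of 2.17 and 2.08, and B#27461 is lower in both irradiated groups, with differences of -2.96 and -2.95.

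In irradiated cells, the ligand's effect was read from combination minus radiation. This comparison holds the ligand's own effect together with any change the ligand makes to the radiation response. The interaction, given below, addresses that change but does not separate it from the ligand's own effect. With a single array per group and design, the interaction also holds measurement noise and culture differences. Combination minus radiation gave the fewest differences, 253 probes higher and 250 lower. In design A the counts were 173 and 166, and in design B 80 and 84. The balance depended on the scaling, with 493 higher and 197 lower after median centring and 175 and 408 from the deposited scores. The largest values came from probes that stood apart on a single array. B#40430 read 198942 in combination and between 257.16 and 295.5 on the other 3 arrays, a difference of 7.61. B#44625 read 172456 against 304.61 to 318.63, a difference of 6.93. These were the 2 values above 65535. At the low end, A#36899 (-4.42) and A#14768 (-4.38) were bright on the radiation array alone, at 2045.0 and 2083.97. Their combination readings, 76.03 and 80.13, lay below that array's lower quartile of 88.335, and with an offset of 50 the differences were -3.83 and -3.81. The differences of B#40430 and B#44625 depended on the scaling, at 9.39 and 8.92 on the log2 scale with cyclic loess, and values above the 16-bit ceiling have no settled scale.

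Probes past 2-fold in the same direction in both ligand differences numbered 21 higher and 75 lower. Independent lists would share 12.5 and 19.5. Median centring gave 40 and 52, and the deposited scores 9 and 193. Another 65 probes went opposite ways, against 32.4 expected from independent lists. In design A there were 61, inside the range of the simulated unchanged probes (mean 75.6, 95% of draws between 58 and 91.0). In design B there were 4, against a simulated mean of 3.74 (between 0 and 7.03). Of the 75, 68 were on design A, where 18.9 were expected, and 7 on design B, where 0.563 were expected. In design A, 17 were higher in both. Simulated unchanged probes gave a mean of 37.4 higher in both (95% of draws between 24 and 51.0) and 37.2 lower in both (between 28 and 49) in design A, so the observed counts lay below and above these ranges. With median centring the design A counts were 32 and 47, inside the ranges simulated for the main setting. For lower in both the simulation gave 1.84 in design B (between 0 and 5). Both directions together, design A had 85 observed against a simulated mean of 74.6 (between 59.0 and 93), and design B 11 against 3.85 (between 1 and 8). As for radiation, these ranges assumed an equal spread on every array, so a count outside them does not by itself show a response. The 10 ranked lowest for ligand were 3.11-fold or more below and 9 of them were on design A. The 10 ranked highest were 2.38-fold to 4.36-fold above, with limma adjusted p-values from 0.187 to 0.496. Across probes, the 2 ligand differences had a Pearson r of 0.06 in design A and 0.12 in design B, with a Spearman rho of 0.06 and 0.18. Of 1722 probes past 2-fold without radiation in design A, 909 (52.8%) had the same sign in irradiated cells, and in design B 161 of 310 (51.9%).

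Both treatments together were compared with untreated cells to read their joint effect. At 2-fold, 526 probes were higher and 780 lower in combination than in control, with 298 and 670 in design A and 228 and 110 in design B. B#16996 and B#27461 were lower, at -3.25 and -2.93 on the log2 scale, near their radiation differences. A#11839 was at -2.33 and B#21243 at 1.97, near their ligand differences. Every comparison with control used the same control array of its design, and these probes were chosen for large differences on the same arrays. Their nearness is therefore no further reading of either effect. The counts against control share that array too, so they are not separate readings. The direction of the majority depended on the scaling and the threshold. Median centring gave 1155 higher and 606 lower, and a 1.5-fold threshold 2260 and 1672.

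The interaction, the ligand's difference in irradiated cells minus that in unirradiated cells, asks whether radiation alters the ligand's effect. It was at least 1 on the log2 scale in 1309 probes and at most -1 in 1238. Design A held 1192 and 911 of them, and design B 117 and 327. The highest values belonged to B#40430 (7.96) and B#44625 (7.04), bright on the combination array alone. The lowest belonged to B#44215 (-6.76) and B#19770 (-5.76), which read 20379.3 and 20132.0 on the ligand array and between 148.85 and 373.59 on the others. Each interaction combines 4 single arrays and has no error estimate. The balance depended on the setting, with 2459 higher and 3488 lower at 1.5-fold, 689 and 291 at 3-fold, 1577 and 771 after median centring, 1821 and 949 from the deposited scores, and 1492 and 771 with cyclic loess. For B#27461 the interaction was 0.01, for B#21243 it was -0.10, and for A#11839 it was 0.49.

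**Figure D4:**
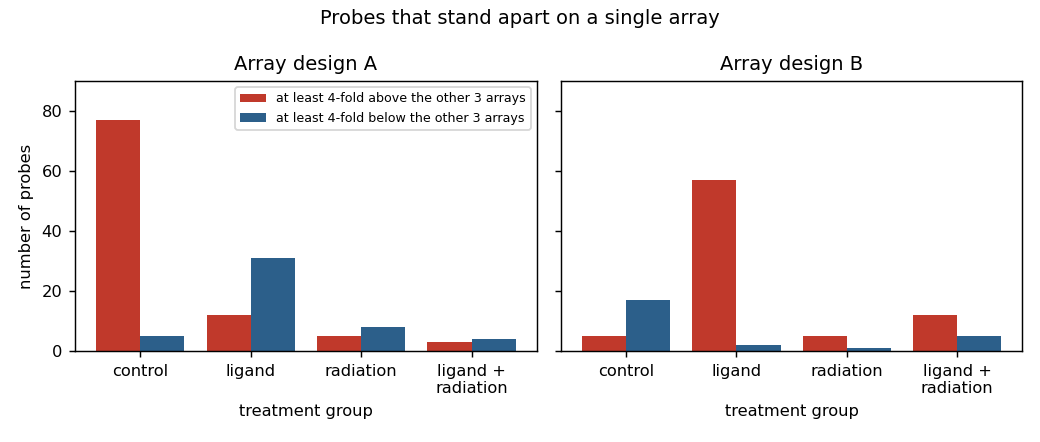
Bars give the number of probes at least 4-fold above (red) or below (blue) all 3 other arrays of their design, by treatment group, for design A (left) and design B (right). The control array of design A had 77 probes above, and the ligand array of design B had 57, against 12 or fewer above on each of the other 6 arrays.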

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

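The interactions were planned, and the tests on the ligand array of design B were chosen after the result was seen. The interactions of B#40430 (7.96) and B#44625 (7.04) drew attention because the ligand's difference had opposite signs without and with radiation. For B#40430 it was -0.35 in unirradiated and 7.61 in irradiated cells, and for B#44625 -0.11 and 6.93. The unirradiated values were of the order of the robust standard deviation between the control and ligand arrays of design B, 0.27. They therefore show no reversal of the ligand's effect. The difference between unirradiated and irradiated values was not tested, as each rests on 1 array per group. With median centring the interactions were 9.81 and 9.09. Both probes read above the 16-bit scanner ceiling of 65535 on the combination array of design B.

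A related pattern appeared on another array of the same design. On the ligand array of design B, 57 probes were at least 4-fold above all 3 other arrays, against 22 on the other 3 arrays together. Of the 86 design B probes at least 4-fold higher with ligand than in control, 1 (1.16%, exact 95% interval 0.0294% to 6.31%) was at least 2-fold higher in combination than in radiation. This does not decide against a ligand response that persists in irradiated cells, since 55 of the 86 were picked for standing above the combination array as well, and the 1 probe was among the other 31, which are not part of the pattern. Bright artefacts on that array, or a ligand response that is absent once cells are irradiated, may account for the pattern and cannot be told apart, because spot positions and a second ligand array of this design were not used here.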

How the results depend on the processing

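Cyclic loess and the exclusion of probes at least 4-fold apart on 1 array were chosen after seeing the data. Of the values of 14 results under the alternatives, 100 stayed within their margin (a factor of 1.5 for total counts, 0.1 for Pearson correlations) and 50 moved beyond it. In 17 of 107 counts the majority turned between higher and lower, and where no reason is given the cause was not tested. The deposited scores keep the order of probes within each array. Quantile normalized, they could therefore hardly differ from the main setting, and all their values are among the 100. Their share of the 107 counts and of the named-probe values below is likewise no check. In these sentences counts join higher and lower probes, and the order is radiation, ligand and combination against control, combination against radiation and against ligand, and the interaction. Without the intensity floor, which doubles the probes tested, the counts were 2148, 3672, 2443, 1034, 1528 and 4970, with 80 for radiation in both differences and 4 limma calls for radiation. With the floor at the 75th percentile, which leaves 9850 probes, radiation, ligand and combination against control gave 507, 1151 and 750, the interaction 1405, radiation in both differences 21, and limma called 26 probes for ligand. At 1.5-fold the counts were 3371, 5195, 3932, 1804, 2710 and 5947, with 245 for radiation and 482 for ligand in both differences. At 3-fold they were 372, 738, 440, 120, 297 and 980, with 8 and 10. Design B alone gave 209, 310, 338, 164, 227 and 444, with 12 and 11 in both differences and 0 limma calls for ligand. An offset of 50 gave 22 and 60 in both differences. The limma calls for ligand, 3 in the main setting, were 0 with median centring, 0 with cyclic loess, 0 with an intensity trend and robust variance, 44 without probes apart on 1 array and 99 with the deposited scores. Those for radiation, 0 in the main setting, were 1 with trend and robust variance, 5 without probes apart on 1 array and 82 with the deposited scores. Limma's prior degrees of freedom moved with these settings. With the deposited scores they were infinite in design B, where all calls from the scores lay. The deposited scores also gave 202 probes for ligand in both differences. Their median over all probes for ligand minus control was -0.29 in design A and 0.34 in design B on their approximate log2 scale, and their counts include that shift. The main setting gave 0.12 and -0.04.

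The share of higher calls depended on the scaling, the threshold and the design. In the main setting it was 37.0%, 41.6%, 40.3%, 50.3%, 65.8% and 51.4% in the order above, and 35.1% for radiation and 21.9% for ligand in both differences. Median centring gave 65.6% for combination minus control, 71.4% for combination minus radiation, 79.4% for combination minus ligand, 67.2% for the interaction, and 58.0% and 43.5% in both differences. The deposited scores gave 21.2% for ligand and 25.2% for combination against control, 30.0% for combination minus radiation, 65.7% for the interaction and 4.46% for ligand in both differences. At 1.5-fold the majority turned to 54.3%, 59.6% and 57.5% higher against control and 41.3% for the interaction. Cyclic loess gave 25.7% for radiation and 25.2% for ligand against control and 65.9% for the interaction. The Pearson correlations of the 2 differences moved by less than 0.1 under every setting that recomputed them, while the Spearman rho for radiation in design A went from -0.26 to -0.14 with median centring. For 16 values of named probes, 80 values under alternatives held 0 reversals, and 17 moved by 0.5 or more on the log2 scale.

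No paired analysis was possible because the labels carry no replicate numbers and each group has 1 array per design. Leaving out an array, an array-design block and gene-level choices were not run, since the designs share no probes and no gene names are paired with them.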

Other observations

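The correlation of the 2 radiation differences was planned, and its use here and the other tests in this part were chosen after the result was seen. Differences from control were wider in design A than in design B, most of all for the ligand, and the cause bears on the 1722 and 310 probes past 2-fold in those designs. In design A, exact multiples of 0.5 made up 30.6% of the values on the ligand array and 7.23% on the control array. They could reflect another scan setting. For design A probes with such a value on either array, the median of control minus ligand was 0.20, against -0.27 for the others. In design B it was 0.13 and 0.03, and why such values went with the direction of the difference was not tested. Design A probes with such a value had a spread of 0.94 in ligand minus control against 0.59 for the others, while in design B the values were 0.28 and 0.27. Leaving out those probes left the spread of ligand minus control 2.19 times as wide in design A as in design B, against 2.43 times with all probes (bootstrap 95% interval of the former 2.09 to 2.32), so this source may add to the excess in design A but is argued against as the whole of it. The negative correlation of the 2 radiation differences in design A, r = -0.257 (bootstrap 95% interval -0.280 to -0.234), does not settle whether a radiation response adds to the ligand response, since opposite deviations of the control and ligand arrays would give it either way. The ratio of design A to design B spread was 1.74 times as large for ligand minus control as for combination minus radiation, and deviations of the control and ligand arrays of design A cannot be told apart from a response in which the treatments do not add up, since each group has 1 array per design.

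The deposited scores gave opposite pictures of the ligand in the 2 designs. Among all probes at least 1 deviation apart from control, 12.02% were higher in design A and 97.3% in design B, a gap of 85.3 percentage points, and among 2-fold calls above the floor the gap was 91.9 points. With each array centred on its own median, the gap was 26.8 points (48.6% and 75.4%) among the former and 59.8 points among the latter. The single median per group, taken over both designs, may account for part of the gap, but how much depends on the threshold and floor, so its share stays open. The median score difference between ligand and control was -0.43 in design A and 0.50 in design B, but centring each group over both designs fixes these opposite signs, so a response of most transcripts in one direction stays untested.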
